A study of Mus musculus with 6 samples.

How the data were processed

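Gene expression was measured by microarray in fibroblasts sorted from the ventral skin of female mice, in 3 wild-type (WT) samples and 3 samples of the K14-PTHrP (KrP) transgenic line, with 1 array per sample. Per the labels' protocols, skin was digested with trypsin and collagenase, cells were pooled before sorting, and viable cells positive for CD140 and negative for CD31, CD45, CD117 and CD49f were collected. Total RNA was isolated on columns with DNase treatment, and 100 ng was labelled with biotin through a whole-transcript expression kit, per the labels' protocols. The labels name 3 mice aged 8 to 12 weeks as the source of cells. They do not say whether these were 3 mice for each sample or for all samples of a genotype. The p-values therefore measure only the spread between these samples, which may be technical.

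The deposited table holds log2 expression values, 1 per probe set and array, made by the authors. RMA and Partek are named in the submitters' processing notes without versions or roles. The values run from 1.72 to 14.32 on the log2 scale, and the deposited array medians lie between 6.34 and 6.43, so no further normalisation was applied in the main fit. A genome build and a filter on probe sets are not given in the sources used here, and no coordinates are printed. Arrays carry no read depth, so the number of arrays limits the precision. The 1105 olfactory receptor genes measured, which fibroblasts are not known to use widely, served as a guide to background. Their median log2 value was 4.07 and their 95th percentile was 6.31, and genes near or below that level have compressed differences. The descriptions of the KrP samples numbered 2 and 3 name another keratin than K14, whereas their source names and genotypes name K14. The latter were used.

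Probe sets were named through the platform annotation. Of 34390 probe sets, 23521 had 1 gene symbol, 1814 had several and 9055 had none there. Of the single-gene probe sets, 23328 were found by gene ID in a RefSeq table of the mouse assembly GRCm38.p6, used for names only, and 193 kept the name of the annotation. Where a gene had several probe sets, which held for 1082 genes, the one with the highest mean over the 6 arrays was taken, leaving 22180 genes. Pthlh, the gene of PTHrP, and Krt5 had no probe set of their own here and were not analysed here as single genes. Closely related genes, such as the H2-Q genes, can share probe signal, and their values are uncertain for the single member named.

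The tests, the gene lists and the rule for named genes were fixed before the data were examined. Differences between KrP and WT were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend on mean level), with 3 arrays per group, no filter and no block. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, with a further count for changes of at least 2-fold. A log2 fold change is the KrP mean minus the WT mean. Of 76 gene lists, 73 had at least 5 measured members and were tested with camera at an inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera was repeated with a correlation estimated per list, and fry was run as a further test. For each list, members passing the test were counted over all genes and adjusted over the list alone. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

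The text names the 15 genes with the largest rise and the 15 with the largest fall among called genes, leaving out predicted genes, small RNAs and receptor segments. It also draws on up to 3 called members per list and direction, on 10 genes set in advance (the hormone and its receptor, sort markers and keratins), and on members of the mammary mesenchyme, dermal papilla and sort marker lists. Genes outside that rule are said to have been chosen after their values were seen.

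Samples in the 2 groups share the replicate numbers 1 to 3. The deviations of each sample from its group mean correlated across genes by 0.414, 0.350 and 0.120 between same-numbered samples, and each sample correlated best with its own number. Every pair lay above 0.1, so the numbers were read as a possible pairing, although genes are not independent replicates. Deviations from a group mean cancel out, so some matching of the samples correlates on balance without any pairing. The value of 0.120 was also close to the 0.067 between WT 2 and KrP 3. That pairing comes from the data and not from a label, so p-values with the block may be too small. The main fit stayed unpaired as planned, and values with the replicate number as a block are given where they change a call or a count stated in the text.

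Further alternatives left out the trend, made the variance prior robust, weighted the arrays, dropped the lower 25% or 50% of genes by mean level, applied quantile normalisation or median centring, averaged probe sets of a gene, or left out each sample in turn. The fit without both samples numbered 2, the one joining a left-out WT 2 with the block, and the estimated correlation with the block were chosen after seeing the data. The same holds for a limma fit over all 34390 probe sets, used for probe sets without a single gene symbol, and for 7 added gene lists. The procedure was tested on simulated data with the means and spreads of the 22180 genes and 3 arrays per group. In 10 simulated sets with 200 changed genes each, it recovered 65.4% of 2-fold and 94.9% of 4-fold changes, and 3.9% of its calls were false. A list of cholesterol synthesis genes shifted by 0.5 on the log2 scale was called in 10 of 10 sets. The simulation was set by means and spreads of single genes, so it does not measure how correlation between genes affects list calls. In the real samples, splits that mixed KrP and WT called up to 14 lists.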

Results

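Fibroblasts were compared between the nipple-like ventral skin of K14-PTHrP (KrP) mice and the ventral skin of their WT littermates, on a C57BL/6 background. In KrP mice the keratin 14 promoter drives parathyroid hormone-related protein (PTHrP) in basal keratinocytes, and PTHrP acts on neighbouring cells through the receptor Pth1r. The question was how the expression profile of dermal fibroblasts differed between these skins. There were 3 KrP and 3 WT samples, each measured on 1 array as log2 values for 22180 named genes. The array medians ranged from 6.34 to 6.43. Correlations between arrays over all probe sets lay between 0.986 and 0.994 within groups and between 0.975 and 0.989 across groups. KrP 2 correlated by 0.989 with each WT array, by 0.986 with KrP 1 and by 0.992 with KrP 3.

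The sorted cells carried fibroblast markers at high levels in both groups. Pdgfra, which encodes CD140a, had a log2 value of 13.23 ± 0.10 in WT and 13.47 ± 0.06 in KrP samples (SD, n = 3 each; adjusted p = 0.144 by limma), and Pdgfrb, which encodes CD140b, had 12.33 ± 0.43 and 12.76 ± 0.36 (adjusted p = 0.428, or 0.0153 with the replicate block). Of the markers excluded by the sort, Ptprc (CD45) lay at 4.85 and 4.65, Kit (CD117) at 6.23 and 6.18, and Pecam1 (CD31) at 6.73 and 6.68, where the 95th percentile of olfactory receptor genes was 6.31. Itga6 (CD49f) lay at 7.41 ± 0.43 and 7.55 ± 0.92. None of these 4 genes passed the test. Pth1r had a log2 value of 7.41 ± 0.13 in WT and 7.50 ± 0.28 in KrP samples (adjusted p = 0.852). Since Pthlh was not analysed here and its transgene is driven in keratinocytes, these samples hold no direct check of the genotype labels.

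**Figure D1:**
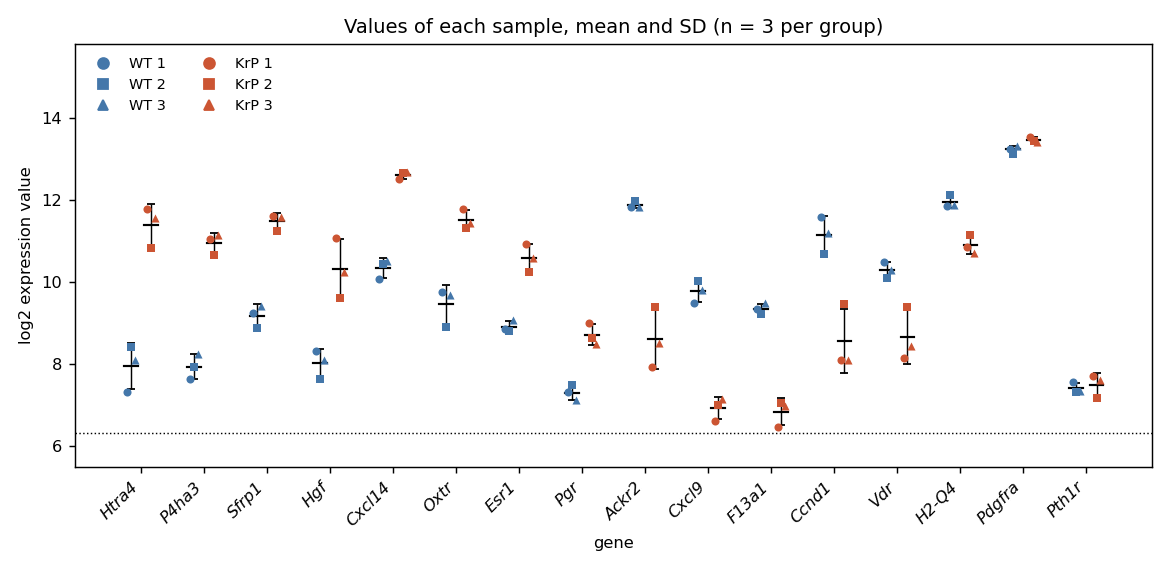
Log2 expression values (vertical axis) of 16 genes (horizontal axis) in each WT (blue) and KrP (orange) sample, with marker shapes for replicates 1 to 3, bars for the group mean and whiskers for the SD (n = 3). The dotted line is the 95th percentile of olfactory receptor genes, 6.31. Htra4 rose from 7.95 to 11.39 and Ackr2 fell from 11.88 to 8.61, while Pdgfra and Pth1r did not pass the test.

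The genes with the largest rise in KrP fibroblasts encoded enzymes, secreted signals and receptors. Htra4, a secreted serine protease, rose 10.9-fold, from a log2 value of 7.95 ± 0.57 to 11.39 ± 0.50 (SD, n = 3 each; log2 fold change 3.44 ± 0.32 SE, adjusted p = 0.00299). P4ha3, a collagen prolyl hydroxylase subunit, rose 8.09-fold (adjusted p = 0.00116), and Moxd1, a copper-dependent monooxygenase, rose 7.96-fold. The urea transporter Slc14a1 had a log2 fold change of 2.63 ± 0.21 and the vasoactive peptide Uts2 of 2.47 ± 0.25. Among secreted signals, the Wnt inhibitor Sfrp1 rose 4.91-fold, the Met ligand Hgf 4.90-fold and the chemokine Cxcl14 4.83-fold. Receptors for peptide hormones rose alongside them, namely the oxytocin receptor Oxtr (4.16-fold, adjusted p = 0.00616) and the PACAP receptor Adcyap1r1 (4.09-fold). The acute-phase protein Saa3 rose 4.01-fold and the prostacyclin synthase Ptgis 3.99-fold. The phosphatase Ptpn5, the kinesin Kif1a and the phosphodiesterase Pde1a completed the 15 largest rises, with log2 fold changes of 2.19, 2.19 and 2.08.

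The largest falls fell on a chemokine scavenger, signalling enzymes and immune-type genes. Ackr2, an atypical receptor that removes inflammatory chemokines, was 9.67-fold lower in KrP samples, at 8.61 ± 0.73 against 11.88 ± 0.09 (SD, n = 3 each; log2 fold change -3.27 ± 0.31 SE, adjusted p = 0.00337). The phosphodiesterase Pde2a was 7.83-fold lower, the adhesion receptor Adgrg2 7.73-fold lower and the cytochrome Cyp2f2 7.18-fold lower (log2 fold change -2.84, or -1.84 with its probe sets averaged). Cxcl9, a chemokine induced by interferon gamma, was 7.23-fold lower (adjusted p = 0.00116). The hyaluronan-degrading protein Cemip had a log2 fold change of -2.69 and cyclin D1 (Ccnd1) of -2.60. Gprc5a, Tmem204 and Apold1 had log2 fold changes of -2.59, -2.57 and -2.32. Genes best known from blood cells were also in this group, with log2 fold changes of -2.52 for the inhibitory receptor Lilrb4a, -2.51 for the clotting factor subunit F13a1 and -2.40 for pleckstrin (Plek). The lipopolysaccharide-binding protein Lbp and the secreted phospholipase Pla2g2e completed the 15 largest falls, at -2.39 and -2.23.

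Over all genes, limma called 483 at an adjusted p under 0.05, of which 255 were higher and 228 lower in KrP samples. At least 2-fold changes made up 263 of them, 138 higher and 125 lower. With the replicate number as a block, 1851 genes passed, 1182 higher and 669 lower, including all 483. Each single sample moved the count, to 230 genes without WT 1, 256 without WT 2, 101 without WT 3, 321 without KrP 1, 1116 without KrP 2 and 85 without KrP 3. In each of the 6 fits that left out a sample, 11 of the 15 largest rises and 8 of the 15 largest falls passed the test. The calls of Hgf (adjusted p = 0.102), Moxd1 (0.0733), Kif1a (0.202) and Pde1a (0.0604) ended without KrP 3, as did those of Adgrg2 (0.0941), Cemip (0.116), Ccnd1 (0.0955), Lilrb4a (0.0875), Lbp (0.117) and Apold1 (0.124). Without WT 3 those of Hgf (0.0871), Kif1a (0.170), Pde1a (0.0693), Adgrg2 (0.0800), Cyp2f2 (0.0529), Cemip (0.10), Ccnd1 (0.0863), Lilrb4a (0.0513), Lbp (0.134) and Apold1 (0.0559) ended. Of the 114 called genes named in the text, 35 passed in every fit that left out a sample, while 48 lost the call without WT 1, 49 without WT 2, 72 without WT 3, 32 without KrP 1, 4 without KrP 2 and 76 without KrP 3. None of the 114 changed direction under any alternative that was run.

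**Figure D2:**
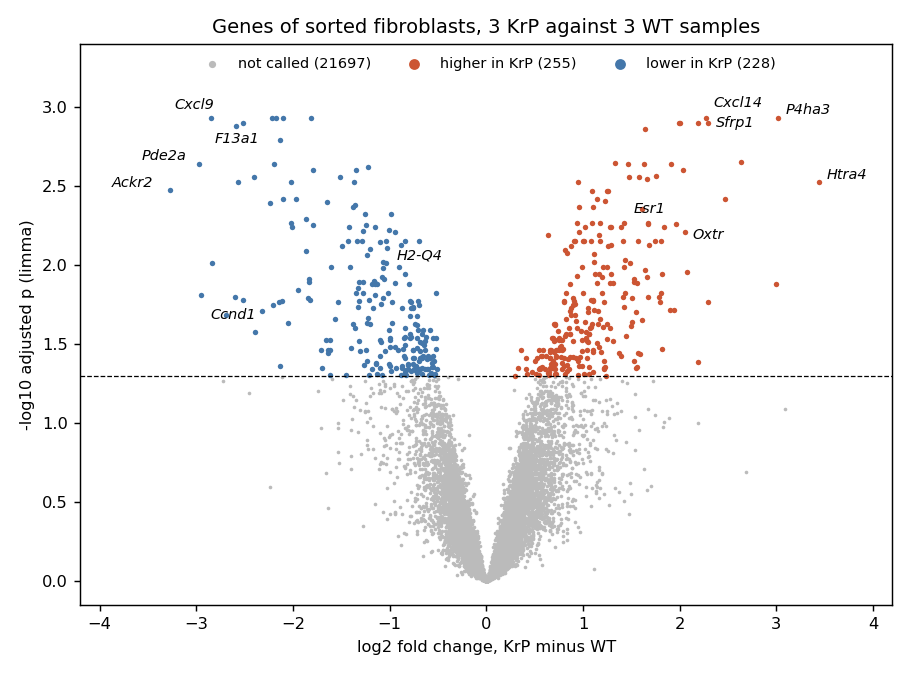
Log2 fold change of each of 22180 genes (horizontal axis, KrP minus WT) against the negative log10 of its adjusted p from limma (vertical axis), with 255 genes called higher in orange, 228 called lower in blue and the others in grey. The dashed line marks an adjusted p of 0.05, and Htra4 lies farthest to the right at 3.44 and Ackr2 farthest to the left among called genes at -3.27.

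Genes that build and modify collagen were higher as a group in KrP fibroblasts. Of 22 measured genes for collagen biosynthesis and crosslinking, 4 rose, 1 fell and 17 did not pass the test (9 rose and 2 fell with the block, and 11 rose and 3 fell when adjusted over the list alone). The risers were P4ha3, the lysyl hydroxylases Plod2 (2.92-fold) and Plod1 (2.42-fold), and the procollagen peptidase Adamts14 (2.31-fold), and Loxl4, a lysyl oxidase, was 1.57-fold lower. Of these, only P4ha3 kept its call under every alternative. Without KrP 3 the limma adjusted p was 0.217 for Plod2, 0.0955 for Plod1, 0.125 for Adamts14 and 0.191 for Loxl4. These calls also ended without WT 3, and that of Plod2 with quantile normalisation (0.0535) and median centring (0.0504). The list passed camera at an adjusted p of 0.00228, and the adjusted p was 0.796 with an estimated correlation. Pan-fibroblast markers passed too (adjusted p = 0.000119, or adjusted p = 0.796 with an estimated correlation), although 0 of 19 passed limma singly (11 were higher at an unadjusted p under 0.05, 8 rose with the block, and 6 rose adjusted over the list alone). Among these, Col1a1 had a log2 fold change of 1.18 ± 0.46 SE (adjusted p = 0.258, or 0.0486 with the block) and S100a4 of 1.08 ± 0.37 (adjusted p = 0.206, or 0.00788 with the block). Both were chosen after their values were seen. Individual matrix genes moved both ways, in lists that camera did not call. Of 19 fibrillar and associated collagens 2 rose and 0 fell (adjusted p = 0.1265), and of 16 other collagens 1 rose and 0 fell (0.908). Of 36 proteoglycan and hyaluronan genes 5 rose and 2 fell (0.258), and of 28 basement membrane genes 2 rose and 2 fell (0.640). With the block these counts were 5 and 0, 2 and 1, 10 and 5, and 3 and 2. Col14a1, Col6a3, the proteoglycan Ogn and the matrix protein Smoc2 rose with log2 fold changes of 1.82, 1.59, 1.67 and 1.63, and the basement membrane collagens Col4a1 and Col4a2 had log2 fold changes of -0.65 and -0.71. Of 39 proteases in the metalloproteinase list, 2 rose and 5 fell (4 and 9 with the block; 6 and 8 adjusted over the list alone). Mmp19 rose 2.37-fold beside Adamts14, and Mmp9, Adamts8 and Mmp13 were 3.65-fold, 2.43-fold and 2.31-fold lower, as were Adamts9 (2.27-fold) and Mmp10 (1.59-fold), chosen after their values were seen. The list gave no call (adjusted p = 0.284). Of 18 protease inhibitors, 4 rose and 1 fell (5 and 1 with the block; 6 and 1 adjusted over the list alone). Timp1, Slpi and A2m rose 2.00-fold, 2.15-fold and 1.71-fold, as did Serpinf1 (1.46-fold), chosen after its value was seen, and Tfpi2 was 4.34-fold lower. That list passed camera at an adjusted p of 0.00819, or an adjusted p of 0.796 with an estimated correlation.

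Signalling genes of the mesenchyme differed as well. Of 16 secreted Wnt inhibitors, 4 rose and 1 fell (6 and 1 with the block; 7 and 1 adjusted over the list alone). Sfrp1, Sfrp4, Dact1 and Sfrp2 rose 4.91-fold, 2.51-fold, 2.14-fold and 1.80-fold, and Dkk2 was 3.93-fold lower. With its probe sets averaged, Sfrp2 had a log2 fold change of 0.49 and lost its call (limma adjusted p = 0.0701). Its call also ended without WT 1, WT 2, WT 3, KrP 1 or KrP 3. The call of Dact1 ended in the same fits, with limma adjusted p from 0.0536 (without WT 1) to 0.154 (without KrP 3). Sfrp1, Sfrp4 and Dkk2 kept their calls under every alternative. Dact1 acts inside the cell, unlike the other members named. The list passed camera at an adjusted p of 0.00351, or an adjusted p of 0.796 with an estimated correlation. Of 17 canonical Wnt target and feedback genes, 0 rose and 2 fell (2 and 4 with the block), without a list call (camera adjusted p = 0.258). Of 22 Wnt ligands and agonists, 1 rose and 0 fell (2 and 1 with the block), also without a call (0.750). Markers of mammary mesenchyme and the nipple sheath passed at an adjusted p of 0.0275 (adjusted p = 0.796 with an estimated correlation), with 2 of 21 members higher and none lower (4 and 1 with the block; 4 and 2 adjusted over the list alone). These were the oestrogen receptor Esr1, which rose 3.19-fold from 8.91 ± 0.15 to 10.59 ± 0.35 (SD, n = 3 each; adjusted p = 0.00545), and the transcription factor Tbx3, which rose 1.56-fold. Other members did not pass without the block, among them Hoxb9 (log2 fold change 1.40 ± 0.33, adjusted p = 0.0836, or 0.0142 with the block), Wnt5a (0.97 ± 0.23, adjusted p = 0.0832, or 0.0171 with the block) and Lef1 (-0.49 ± 0.13, adjusted p = 0.111, or 0.0458 with the block). This list lost its call without WT 2 (adjusted p = 0.290) and without KrP 1 (0.0562). BMP target genes passed at an adjusted p of 0.0319 (adjusted p = 0.796 with an estimated correlation), with 1 of 13 members called, Atoh8 at 2.63-fold (3 rose and 1 fell with the block; 7 and 1 adjusted over the list alone). The call ended without WT 2 (adjusted p = 0.0609) and without KrP 1 (0.0516). Factors that act on melanocytes passed at an adjusted p of 0.0353 (adjusted p = 0.796 with an estimated correlation), and 3 of 11 rose, namely Hgf, Fgf2 (2.14-fold) and Sfrp2 (4 rose with the block and adjusted over the list alone). That call ended without WT 1 (adjusted p = 0.135) and without KrP 2 (0.142).

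Hormone and growth factor genes changed in both directions. Of 21 steroid and nuclear hormone receptors, 3 rose and 3 fell (4 and 3 with the block; 4 and 5 adjusted over the list alone; camera adjusted p = 0.583). Beside Esr1, the progesterone receptor Pgr rose 2.66-fold and the orphan receptor Nr2f2 1.87-fold. The vitamin D receptor Vdr was 3.10-fold lower, the thyroid hormone receptor Thrb 1.65-fold lower and the fatty acid sensor Ppard 1.56-fold lower. Vdr also belonged to the list of PTHrP and calcium hormone signalling, in which 1 of 19 members rose and 4 fell (1 and 5 with the block; 1 and 4 adjusted over the list alone). The members that fell included Cyp27b1, which makes active vitamin D (4.16-fold lower), Tnfrsf11b, the decoy receptor osteoprotegerin (3.06-fold lower), and the receptor Calcrl (2.54-fold lower), chosen after its value was seen. Ramp3, a partner of calcitonin family receptors, rose 3.52-fold. The list was called lower at an adjusted p of 0.0353, or an adjusted p of 0.796 with an estimated correlation, and the call ended without WT 2 (adjusted p = 0.150) and without KrP 3 (0.0682). Since Pthlh was not analysed and Pth1r did not pass, this call does not measure PTHrP signalling itself. The list of 20 cAMP and CREB responsive genes was not called (camera adjusted p = 0.640, median -0.04). Of its members 1 rose and 1 fell (4 and 5 with the block, 4 and 3 adjusted over the list alone). In the IGF axis, 3 of 16 members rose and 2 fell (6 and 2 with the block; 5 and 2 adjusted over the list alone; camera adjusted p = 0.379). Igf1, the binding protein Igfbp6 and the protease Htra1 rose 3.36-fold, 2.48-fold and 2.04-fold, and Igfbp2 and the receptor Igf2r were 3.60-fold and 1.62-fold lower. Of 24 dermal papilla and sheath markers, Sox18 alone passed (3.88-fold higher), and with the block 3 rose and 3 fell (5 and 2 adjusted over the list alone without it; camera adjusted p = 0.591). Fgf10 in that list had a log2 fold change of 1.53 ± 0.45 (adjusted p = 0.148, or 0.0122 with the block). The Notch target Hes1 was 2.86-fold lower, the 1 called gene of 17 in the Notch list, also with the block and adjusted over the list alone (camera adjusted p = 0.493).

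Transcription factors of dermal patterning were lower as a group. Of 37 measured, 1 rose and 3 fell (4 and 7 with the block; 3 and 8 adjusted over the list alone). Meox2, Eya1 and Foxd1 had log2 fold changes of -1.32, -1.04 and -0.70, while Tbx3 rose. The KrP means of Meox2 (6.26) and Foxd1 (5.71) lay under the 95th percentile of olfactory receptor genes, 6.31. The list passed at an adjusted p of 0.0353 (adjusted p = 0.796 with an estimated correlation), and the call ended without WT 1 (adjusted p = 0.0733) and without KrP 3 (0.127).

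Antigen presentation genes were lower in KrP fibroblasts. Of 16 measured, 2 fell and none rose (3 fell with the block; 7 fell adjusted over the list alone). Nlrc5, which activates class I genes, was 2.54-fold lower, at 6.88 ± 0.08 against 8.22 ± 0.11 (SD, n = 3 each; adjusted p = 0.00251). The class I gene H2-Q4 was 2.06-fold lower, with the limit that its probes can take signal from its close relatives. Its call ended without WT 3 (limma adjusted p = 0.0542) and without KrP 3 (0.0604). The list was called lower at an adjusted p of 1.9e-05, or an adjusted p of 0.796 with an estimated correlation. Of 26 interferon response genes, 3 fell and none rose (4 fell with the block and adjusted over the list alone). These were Cxcl9, the GTPase Iigp1 (4.41-fold lower) and the guanylate-binding protein Gbp3 (log2 fold change -0.76), without a call for the list (adjusted p = 0.111). Among 28 chemokines, Cxcl14 rose and Cxcl9 and Ccl5 fell, with Ccl5 2.73-fold lower (3 rose and 6 fell with the block; 2 and 2 adjusted over the list alone). The chemokine list missed the threshold at an adjusted p of 0.0557 and passed as lower with the block (0.0318), though not with an estimated correlation and the block (adjusted p = 0.813). In the complement and coagulation list, F2r, the thrombin receptor, was 3.52-fold lower beside F13a1, complement factor B (Cfb) was 2.18-fold lower and Gas6, a ligand of TAM receptors, was 1.94-fold higher. In all, 1 of its 30 members rose and 3 fell (3 and 7 with the block; 2 and 5 adjusted over the list alone; camera adjusted p = 0.222). Without KrP 3, among other samples, the calls of Iigp1 (limma adjusted p = 0.116), Gbp3 (0.132), Ccl5 (0.214) and Cfb (0.226) ended. Markers of immune cells gave no list call (adjusted p = 0.212 for macrophage and dendritic cells and 0.212 for lymphoid cells). Of 20 macrophage and dendritic cell markers, Csf1r alone passed and was 1.66-fold higher (2 rose with the block; 1 rose adjusted over the list alone).

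**Figure D3:**
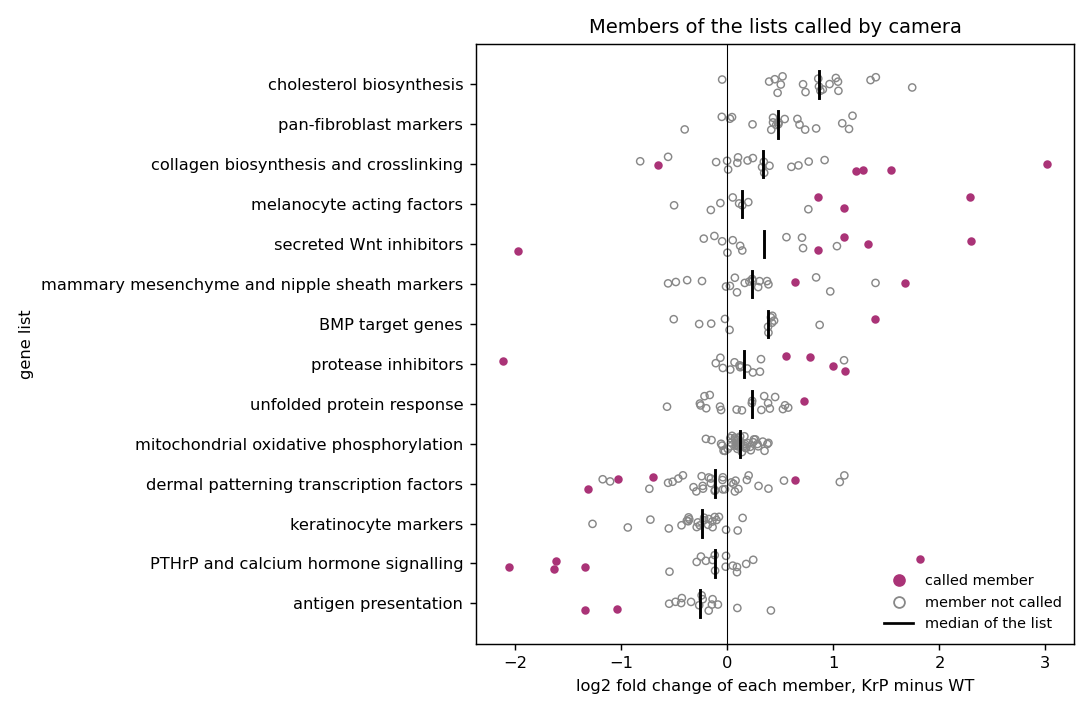
Log2 fold changes (horizontal axis, KrP minus WT) of the members of the 14 gene lists called by camera (vertical axis), with filled points for members called by limma, open points for the rest and black bars for list medians. Cholesterol biosynthesis had the highest median, 0.86, with no called member, and antigen presentation the lowest, -0.25, which was called lower.

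Genes for making cholesterol were higher together, although none passed singly. Of 19 measured members, 18 had a positive log2 fold change and the list median was 0.86 (camera adjusted p = 1.4e-09, or adjusted p = 0.796 with an estimated correlation). None was called over all genes by limma, 15 were higher at an unadjusted p under 0.05, 12 rose with the block, and 14 rose when adjusted over the list alone. The largest differences, chosen after their values were seen, were in squalene synthase Fdft1 (1.74 ± 0.43 SE, adjusted p = 0.0894, or 0.00664 with the block) and the demethylase Cyp51 (1.40 ± 0.29, adjusted p = 0.0542, or 0.0122 with the block). Oxidative phosphorylation genes had a small joint difference, with a median of 0.12 over 42 members. Limma called none of them over all genes, with the block or adjusted over the list alone, and 7 were higher at an unadjusted p under 0.05. That list passed at an adjusted p of 0.00541 (adjusted p = 0.796 with an estimated correlation), and the call ended without WT 3 (adjusted p = 0.0728) and without KrP 1 (0.112). The unfolded protein response list passed at an adjusted p of 0.0353 with 1 of 21 members called, Sdf2l1 at 1.65-fold (3 rose with the block; 9 rose adjusted over the list alone). It lost the call with the block (adjusted p = 0.131), with an estimated correlation (adjusted p = 0.796), without WT 1 (0.364), without KrP 1 (0.0901) and without KrP 3 (0.185). Lipoprotein lipase (Lpl), which releases fatty acids from lipoproteins, was 3.46-fold lower and Gpam, which starts triglyceride synthesis, was 2.06-fold higher, while the list of fatty acid synthesis and uptake gave no call (adjusted p = 0.284; 1 rose and 1 fell of 23, 7 and 2 with the block, 5 and 1 adjusted over the list alone).

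Keratinocyte markers were lower as a list in KrP samples, and that call depended on a single WT sample. Limma called none of 24 members over all genes, with the block or adjusted over the list alone, 1 was lower at an unadjusted p under 0.05, and the list was called lower at an adjusted p of 0.00351 (adjusted p = 0.796 with an estimated correlation). Without WT 2 the adjusted p was 0.237 and the mean difference moved from -0.31 to -0.06, and 17 of the 24 markers were highest in WT 2. Krt14 lay at 6.96 ± 0.56 in WT and 6.60 ± 0.07 in KrP samples (SD, n = 3 each; adjusted p = 0.532). A probe set shared by Krt5 and Krt6a had a log2 fold change of -0.36 ± 0.29 SE. WT 2, a sample that entered every comparison above, was highest by mean in 12 of the 18 cell type lists, and its quartiles were the narrowest of the 6 arrays (5.18 and 8.17).

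**Figure D4:**
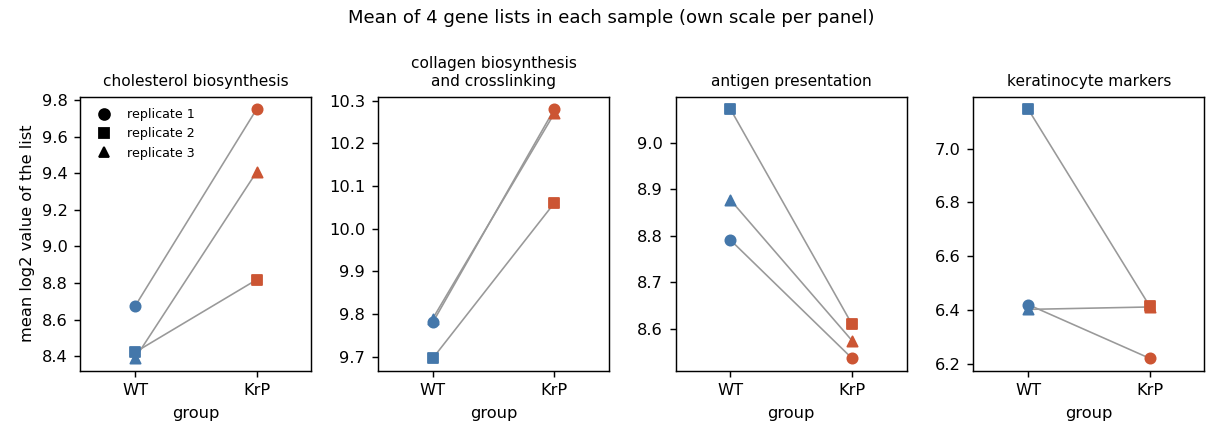
Mean log2 value of the members of 4 gene lists (vertical axes, 1 scale per panel) in each WT and KrP sample (horizontal axis), with lines joining samples of the same replicate number. Cholesterol genes were higher in the KrP sample of every number, by 1.08, 0.40 and 1.02, while the keratinocyte mean of WT 2, 7.15, stood above those of the other 5 samples, which lay between 6.22 and 6.42.

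In total 10 lists were called higher and 4 lower by camera at the preset correlation, and none with a correlation estimated from these samples, where 3 had an unadjusted p under 0.05. The fry test, which asks whether the genes of a list move on balance one way, called none of the 73 lists, and 18 had an unadjusted p under 0.05. Its test for change in either direction called 56. Lists for olfactory receptors (adjusted p = 0.852), Y-linked genes (0.869) and cytosolic ribosomal proteins (0.909), where no difference was looked for, were not called. Mean, median and camera direction disagreed in sign in 10 lists, none of which was called.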

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

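The fit over all probe sets reported in this part was not among the planned tests and was added after seeing the data. Probe sets that the comparisons above left out, since they carried no gene symbol or several, also held differences between KrP and WT samples. In a limma fit over all 34390 probe sets, which called 384 at an adjusted p under 0.05, 29 of the 9055 probe sets with no symbol passed, 14 higher and 15 lower in KrP samples. Of the 1814 probe sets with several symbols, 15 passed, 6 higher and 9 lower. Several of the latter cover families of interferon-inducible and class I genes. A probe set shared by H2-Q6 and H2-Q8 had a log2 fold change of -1.56 (adjusted p = 0.00520), and a pair shared by H2-Q7, H2-Q8 and H2-Q9 had -1.03 and -1.30. A probe set of the Gvin1 family had -1.78 and a probe set shared by Olfr56 and Ifi47 had -1.53. These values belong to the families and not to a single gene, and they were not used in the comparisons above.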

How the results depend on the processing

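The fits without both samples numbered 2, without WT 2 with the replicate block, and with an estimated correlation with the block were chosen after seeing the data, and the others were planned. Among 114 called genes named in the text, 1612 of 1934 combinations of gene and alternative kept direction and call, 322 lost the call and 0 changed direction. The 14 called lists kept the call in 177 of 266 combinations and lost it in 89. The count of 483 genes moved to 6410 with array weights (3759 higher, 2651 lower; 508 at least 2-fold, 291 and 217), and to 1851 with the replicate block (1182 and 669; 423 at least 2-fold, 231 and 192). It moved to 890 without both samples numbered 2 (496 and 394; 489 at least 2-fold, 279 and 210), and to 896 without WT 2 with the replicate block (545 and 351; 481 at least 2-fold, 285 and 196). Leaving out 1 sample at a time gave 85 to 1116 genes, 45 to 682 higher and 40 to 434 lower, and 78 to 514 at least 2-fold, 40 to 308 higher and 38 to 206 lower. The cause of these moves was not tested. Other planned settings gave between 439 (median centring) and 548 genes (lower 50% of genes dropped).

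The count of 14 lists moved to 9 with array weights (2 lower) and to 4 without the lower 50% of genes by mean level (3 higher, 1 lower). It was 0 (0 higher, 0 lower) with an estimated correlation, with fry one way and with an estimated correlation joined to the block. Without both samples numbered 2, and without WT 2 with the block, 2 lists were lower. Leaving out 1 sample gave 10 to 16 lists, 7 to 11 higher and 2 to 6 lower. The cause of these moves was not tested. Calls of cholesterol synthesis, antigen presentation, pan-fibroblast markers and Wnt inhibitors passed under every setting but the estimated correlation and fry. Beyond the calls given here, above or below, with their blocked values, the replicate block changed no other call of a list or of a gene named in the text.

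Genes that changed sign were never called. Pecam1 had a log2 fold change of 0.11 with array weights, -0.17 to 0.15 when 1 sample was left out, 0.20 without both samples numbered 2 and 0.20 without WT 2 with the replicate block. Kit had 0.17 with array weights, -0.20 to 0.06 when 1 sample was left out (0.00 without WT 1), 0.08 without both samples numbered 2 and 0.08 without WT 2 with the replicate block. With 1 sample left out, Pth1r ranged from -0.01 (without KrP 1) to 0.25, and Itga6 from -0.16 (without KrP 2) to 0.68, with -0.08 without KrP 3. The cause was not tested. A pseudocount was not varied, since the values are on the log2 scale as deposited, and camera offers no robust variance prior, so that setting gave no list value. Genes near the olfactory receptor level of 6.31 have compressed differences. Among called genes named in the text, Meox2, Foxd1, Lilrb4a (5.89), Tek (5.76), Rarres1 (5.90) and Mpeg1 (5.93) had KrP means under that level. A2m had a WT mean under it (6.27).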

Other observations

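The tests of the added gene lists, of the patterns weighed here and of the splits of samples were chosen only after the results were seen, while the fixed lists were planned. Growth factor and guidance genes moved both ways in KrP fibroblasts. Of 20 PDGF and VEGF ligands and receptors, 3 rose and 2 fell (4 and 4 with the block; 4 and 5 adjusted over the list alone; camera adjusted p = 0.798). Vegfd, Flt1 and Pdgfc rose 2.89-fold, 2.10-fold and 1.86-fold, and Tek and Nrp2 were 1.69-fold and 1.64-fold lower. Of 25 FGF ligands and receptors, Fgf2 rose and the receptors Fgfr2 and Fgfr1 were 2.18-fold and 1.43-fold lower (camera adjusted p = 0.475; 4 rose and 4 fell with the block; 4 and 3 adjusted over the list alone). In the TGF-beta and activin pathway, the activin subunit Inhbb rose 2.68-fold and the latent binding protein Ltbp3 1.82-fold, while Tgfb1 was 2.13-fold lower (2 rose and 1 fell of 20; 3 and 5 with the block; 3 and 3 adjusted over the list alone; camera adjusted p = 0.591). Cyp26b1, which degrades retinoic acid, was 3.06-fold lower and the retinoid-responsive gene Rarres1 1.62-fold lower, the 2 called genes of 15 in that list (1 rose and 3 fell with the block and adjusted over the list alone; camera adjusted p = 0.345). Among axon guidance genes Sema3a rose 2.03-fold and Efnb1 and Epha4 were 2.01-fold and 1.58-fold lower (1 rose and 2 fell of 30; 6 and 6 with the block; 6 and 7 adjusted over the list alone; camera adjusted p = 0.583). Each of these genes lost its call without KrP 3, with adjusted p between 0.0610 for Tek and 0.223 for Fgf2.

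Single genes outside the rule for named genes were chosen after their values were seen, and no list tests them as a group. Arhgdib was 4.64-fold lower, Mpeg1 4.06-fold lower, Syk 3.55-fold lower and the checkpoint ligand Cd274 3.25-fold lower. The call of Syk ended without WT 3 (adjusted p = 0.0693) and without KrP 3 (0.114), and that of Cd274 without KrP 3 (0.191) and 4 other samples. The proteoglycan Sdc1, a called list member within that rule, rose 2.01-fold, with its call lost without WT 3 (0.0559) and KrP 3 (0.0659). In an added list of 17 receptors for reproductive and pituitary hormones, 4 rose and 1 fell (6 and 1 with the block), with a camera adjusted p of 0.0128, or adjusted p = 0.141 with an estimated correlation. Members of that kind outside the rule included the relaxin receptor Rxfp1, 3.49-fold higher, and the growth hormone receptor Ghr, 1.87-fold lower. Their calls ended without WT 3 (adjusted p = 0.0545 and 0.0759) and without KrP 3 (0.101 and 0.0929). An added list of 26 inflammatory genes driven by NF-kB was lower (adjusted p = 1.1e-07, or adjusted p = 0.394 with an estimated correlation), with 1 member higher and 1 lower by limma (1 and 14 with the block). The planned list of 28 cytokines and inflammatory mediators was not called (camera adjusted p = 0.698). Of its members 1 rose and 1 fell by limma (3 and 6 with the block). An added list of 22 SRF and actin cytoskeleton genes was not called (camera adjusted p = 0.0987), with 0 members called by limma (3 rose with the block). The added lists that were called here were picked after the called genes had been seen and are not independent evidence of their direction.

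Keratinocyte markers were lower in KrP samples as a list, with a mean difference of -0.31, although the list had an adjusted p of 0.796 with an estimated correlation; WT 2 was highest by mean in 12 of the 18 cell type lists, and its array had the narrowest quartiles (5.18 and 8.17). A narrower range of values in that array is argued against as the whole cause. The markers exceeded the mean of WT 1 and WT 3 by a median of 0.562. That was above each of 10000 random lists of similar level in KrP samples (95th percentile 0.185), and the other cell type lists reached 0.295 at most. Several of those lists also passed that 95th percentile, among them melanocyte (0.23) and Schwann cell markers (0.22). Random lists are therefore a loose reference for marker lists in WT 2, and the keratinocyte list was weighed after it had stood out there. Keratinocyte RNA in WT 2 is a candidate explanation for the excess of keratinocyte markers there, and it was not tested. The list's camera adjusted p of 0.237 without that sample shows only that the call rested on WT 2. It would weaken in that way whatever had raised the markers there. Krt17 lay at 9.06 in WT 2 against 5.60 to 6.10 in the others. It was chosen after its value was seen and had the largest excess of the 24 markers, at 3.05. The sort kept CD140-positive, CD49f-negative cells, which should remove basal keratinocytes, and Itga6 (CD49f) itself was not highest in WT 2 (7.91, against 8.16 in KrP 2 and 8.01 in KrP 3), so how such RNA entered is not explained, nor is the rise of the other cell type lists. Whether all WT samples held more keratinocyte RNA stays open, since the mean difference without WT 2 was -0.063, still below 0 and without a call.

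Cholesterol synthesis genes were higher in the KrP sample of every replicate number, by 1.08, 0.40 and 1.02, although the list had an adjusted p of 0.796 with an estimated correlation. More stress during the preparation of KrP samples may contribute and stays open, since the heat shock list had a mean difference of 0.284 without a call (adjusted p = 0.475). Its median was 0.045, with 8 members higher and 6 lower, and limma called 1 higher (3 with the block). A lower sterol load of KrP fibroblasts, a biological candidate explanation, stays open too. The 9 measured LXR targets other than Abcg1 had a median of 0.133 and a mean of -0.21, with members moving both ways. Of these, 0 were called (1 rose and 2 fell with the block). Abcg1, chosen after its value was seen, was 2.70-fold lower, a call that ended without WT 3 at an adjusted p of 0.0511.

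Antigen presentation genes were lower in KrP samples, and of 31 genes of the interferon gamma type, a list picked on these samples, 12 fell (16 with the block; camera adjusted p = 2.5e-21, but adjusted p = 0.141 with an estimated correlation, and 0.796 for antigen presentation). A fall of all interferon response genes stays open. The fixed list of 26 had a median change of -0.0567 with members moving both ways (12 higher, 14 lower, quartiles -0.43 and 0.18), against a median of -0.25 over the antigen presentation list. The 18 type I members of the fixed list, set apart after the values were seen, had a median of 0.113 (12 higher, 6 lower, 0 called). That subset held as many higher members as the whole fixed list and left out the called members, which all fell. Its median was therefore shaped by the choice of members and cannot weigh against a general fall. Fewer immune cells in KrP samples stay open: the sort removed CD45-positive cells, Ptprc (CD45) lay at 4.85 and 4.65, neither immune list was called (adjusted p = 0.212 each) and 0 of 32 immune cell markers fell as much as H2-Q4, but those markers had a median WT level of 6.01, under the olfactory receptor level of 6.31, and Plek, F13a1 and Arhgdib, picked after their falls were seen, fell from 9.73, 9.35 and 10.03. The class I gene H2-K1, chosen after its value was seen, had a log2 fold change of -0.55 (adjusted p = 0.0857, or 0.0148 with the block), and the H2-Q genes may share probe signal. A lower interferon gamma input to KrP fibroblasts is a hypothesis that these arrays leave open, since the source of interferon gamma was not analysed here.

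Esr1 and Pgr rose, and so did Greb1, a target of the oestrogen receptor chosen after its value was seen (2.63-fold; the call ended without KrP 3, adjusted p = 0.154, and without WT 1, WT 2 and WT 3, up to 0.159). The hypothesis that oestrogen response genes rose more widely was tested on 19 others, with Igf1 and Ramp3, called higher at 3.36-fold and 3.52-fold, left out beforehand as well. The 19 had a median change of 0.0833 and a mean of -0.06 (camera adjusted p = 0.524). By limma 0 rose and 1 fell (4 and 3 with the block). The members moved both ways, among them Ccnd1, the 1 that limma called lower, and since the list left out called genes, the test excludes nothing and the hypothesis stays open.

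The 6 samples can be split into 3 and 3 in 10 ways, so no share under 0.05 can be reached. For called genes 1 of the 10 splits, the real one with 483, gave as many, and the highest other gave 0, with 306 to 2584 genes at an unadjusted p under 0.05. For called lists 2 of the 10 splits gave as many as the real 14, since the split that set WT 1, WT 2 and KrP 2 against the rest also called 14. Further splits that mixed the groups called 13, 11, 9 and 6 lists. The count of lists called by camera at the preset correlation therefore did not set the real grouping apart from splits that mix the groups. Among the 4 splits that part all 3 replicate numbers, the other 3 called 1, 5 and 2 lists and, with the replicate block, 0 genes against 1851. Splits that mix the groups put the difference between KrP and WT into the spread within each side. Low gene counts there arise whatever made the groups differ, and lend the real split no support. The block was also read from deviations around the real group means.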
